A study of Mus musculus with 6 samples.

How the data were processed

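The study profiled messenger RNA of sorted cardiac macrophages from Lgmn KO and WT mice, with 3 libraries each, and samples were placed in groups by the titles and genotype labels. Per the labels' protocols, hearts were digested with enzymes, passed through a strainer, and stained with antibodies to CD45, CD64 and CD11b and a dye that excludes dead cells. Total RNA was purified and libraries were prepared with standard Illumina protocols, per the labels' protocols, which name neither the kit nor whether strand was kept. The submitters' processing notes list HISAT2, TopHat2 2.0.9 and TopHat without saying what each did, and name the build hg38, a human one. The positions in the table are those of mouse: 98.8% of its 34745 gene IDs are in GENCODE M21 (GRCm38), and 80.9% of the matched genes have the same chromosome, start and end there. Coordinates are therefore given as in the table and read as GRCm38. The read counter, its strand setting and the authors' test are not given in the sources used here.

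A single table of all 6 samples was used, and each sample's columns were matched by name to the sample titles. Per the file headers it holds a count and an FPKM value (fragments scaled to gene length and library size) per gene and sample. The deposited counts are whole numbers that sum to different totals, so they were taken as raw read counts per gene. The deposited FPKM values equal count divided by a gene length and by the column's total: in 100% of the 9082 genes with at least 100 counts in every library the implied length was the same whole number of bases within 0.5 bases. FPKM was not tested. The authors' group means of FPKM, their log2 fold change of Lgmn KO over WT, and their p-value and q-value per gene are also deposited, per the file headers, and were only described and counted, never mixed with values computed here. All 34745 rows name a gene.

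Depth was 20369763, 19546253 and 21462640 counts for Lgmn KO replicates 1, 2 and 4 and 20158494, 21648172 and 24086976 for WT replicates 1, 2 and 3. The 10 most abundant genes took 17.0% to 18.5% of each library. Pairs of libraries of one group differed by 14.0 to 42.7 times the sampling noise (chi-square over its degrees of freedom, genes with at least 10 counts in the pair), more than repeat reads of the same library would. Each was therefore counted as a library of its own, which does not show that it came from a separate animal. The common biological coefficient of variation was 16.1%.

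Genes were kept by edgeR's filterByExpr, scaled by TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, Lgmn KO against WT with no covariate, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Levels are CPM, counts scaled to library size with TMM factors, given as mean ± SD of 3 libraries, and fold changes are fitted with their standard error from the F statistic. Where a gene had 0 counts in all libraries of a group, its fold is a lower bound against 3 counts over that group. A set of 32 gene lists with 906 members (895 found by symbol, 6 by synonym, 5 not found), which cover the lysosome, phagocytosis, macrophage states, other cell types and RNA quality, was chosen from textbook knowledge and tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry, with adjustment over the 32 lists. Calls within 5 Mb of Lgmn were compared with the rest by Fisher's exact test.

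The genes named in the text follow a rule. It takes Lgmn, then in each direction the 10 called genes with the largest fold change, a mean of at least 5 CPM and groups that do not overlap, leaving out predicted genes, pseudogenes by name and receptor segments. From each list it adds the 3 members of smallest p and the 2 of highest mean, of which 2 to 4 are printed. Results on a few genes that the rule names are not reported here. Genes named outside the rule are said to be so where they appear. Tests, lists, alternatives and this rule were fixed before the data were examined, apart from those named as chosen later.

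The procedure was tested on simulated data: counts were drawn from the real means and library sizes with known changes. In the simulated Lgmn KO against WT comparison of 12388 genes it recovered 75.5% of 98 genes changed 2-fold and 95% of 100 changed 4-fold, none in the wrong direction, with 10 unchanged genes among the calls. With no change simulated, 2 of 12381 genes and 0 lists were called, and a list of 12 genes lowered 2-fold was called lower in a simulation of 12383 genes. Genes were drawn independently of each other, so the 0 lists do not give the rate of false list calls in the real libraries. There the splits that mix Lgmn KO and WT called 2 to 16 lists with the preset correlation and 0 with an estimated one. Each such split mixes the genotypes unequally and keeps part of their difference, so it does not give that rate either.

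Alternatives were DESeq2 1.42.0 size factors in place of TMM, no filter, a filter of at least 10 counts on average, DESeq2's Wald test, limma with sample weights, the replicate number as a block, each library left out in turn, a threshold of 0.1 or a 2-fold minimum, a window of 20 Mb, and the authors' q-value with a 2-fold minimum. The filter was run again in each fit without 1 library, so the tested members of a list can differ between fits. Alternatives that apply only to normalized values (quantile normalization and pseudocounts) were not run, because the table holds counts. Chosen after seeing the data were limma-voom without weights, edgeR's robust quasi-likelihood fit and edgeR's exact test. Figures were drawn with matplotlib 3.10.9.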

Results

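Messenger RNA was sequenced from cardiac macrophages of mice without legumain (Lgmn KO) and of wild-type mice (WT), taken after myocardial infarction. Legumain is an asparaginyl endopeptidase of the lysosome, the organelle in which macrophages break down engulfed material. The comparison asks which macrophage transcripts differ when the enzyme is missing, in a study on how cardiac macrophages clear dying heart muscle cells. The mice were C57BL/6 and 8 weeks old. Hearts were digested with collagenase, elastase and DNase, and the cells were stained for CD45, CD64 and CD11b, surface proteins that together mark leukocytes, macrophages and myeloid cells. The labels mention both coronary artery ligation and sham surgery without saying which each animal had, and the series design places all samples after infarction. Lgmn KO had 3 libraries (replicates 1, 2 and 4) and WT had 3 (replicates 1, 2 and 3). The labels do not say that each library came from a separate animal, so p-values measure only the spread between libraries, which may be technical. Total counts per library lay between 19546253 and 24086976. At these depths a gene with 0 counts in a library could still hold up to 0.125 to 0.153 CPM (counts scaled to library size), which is 3 counts and covers counting error only. Of 34745 genes listed, 18457 had a count in at least 1 library and 12546 were tested.

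Lgmn itself fell in every Lgmn KO library. Its level was 83.5 ± 4.91 CPM (SD, n = 3) in Lgmn KO and 2391 ± 263 CPM (SD, n = 3) in WT, a log2 fold change of -4.84 with a standard error of 0.11 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.23e-06). The Lgmn KO libraries kept 3.29%, 3.70% and 3.49% of the WT mean, and the WT libraries held 2205, 2692 and 2277 CPM. Lgmn (ENSMUSG00000021190) lies on chromosome 12 from 102394084 to 102439813 on the minus strand in the mouse build the table follows (GRCm38), and is protein coding. The part of the gene removed in these mice is not given in the sources used here, so the reads that remain are given as a value only.

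Besides Lgmn, single genes of antigen presentation, inflammation and matrix breakdown fell in the Lgmn KO libraries, and a smaller number of genes rose. The lists of these 3 groups were called lower with a preset correlation between genes and not with an estimated correlation (adjusted p = 0.435, 0.435 and 0.544). Among the genes of MHC class II presentation Cd74, the invariant chain, was at 107 ± 8.37 CPM in Lgmn KO and 1181 ± 692 CPM in WT (SD, n = 3 each). The gelatinase Mmp9 fell by 2.41 on the log2 scale. Nin, which encodes the centrosome protein ninein, rose from 130 ± 9.37 to 315 ± 15.0 CPM (SD, n = 3 each). In all, 99 genes passed an adjusted p of 0.05, of which 39 were higher and 60 lower in Lgmn KO, and 61 of them differed at least 2-fold (19 higher, 42 lower). Among all tested genes 23.7% had groups that did not overlap, where chance gives 10% for 3 against 3. The first principal component of log2 CPM, with 47.6% of the variance, placed all Lgmn KO libraries (-39.5, -21.0 and -19.2) on one side of all WT libraries (11.7, 42.5 and 25.4). The number of genes depended strongly on single libraries, with 26, 6 and 27 genes passing without Lgmn KO replicate 1, 2 or 4 and 639, 35 and 14 without WT replicate 1, 2 or 3. Only 4 of the 99 genes kept their call in all of these fits. All 99 kept their sign, but their groups did not overlap, so leaving out 1 library could not reverse it. DESeq2's Wald test gave 804 genes, limma with sample weights 340, edgeR without a filter on low counts 318 and a threshold of 0.1 gave 503. Of the tests chosen after the data were seen, limma-voom without sample weights gave 46 and edgeR's exact test 709.

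**Figure D1:**
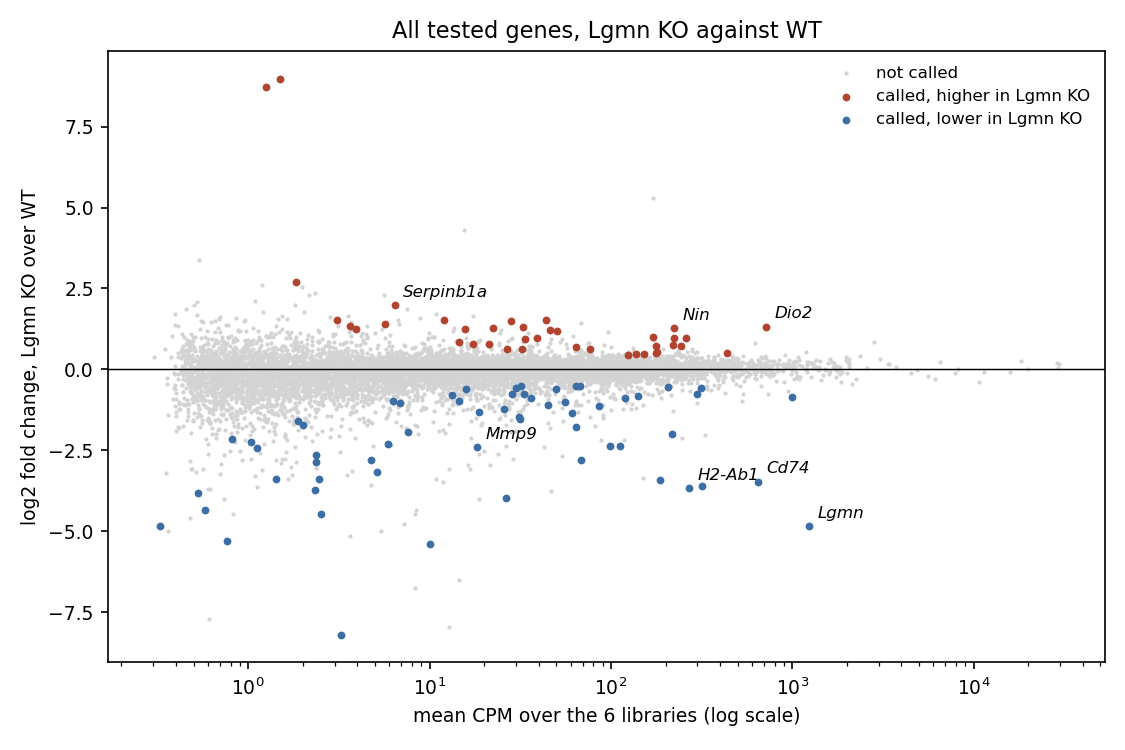
Log2 fold change of Lgmn KO over WT (vertical axis) against mean CPM of the 6 libraries (horizontal axis, log scale) for the 12546 tested genes; red points are the 39 genes called higher, blue points the 60 called lower and grey points the rest. Lgmn stands at -4.84 among the highly expressed genes, and the 2 red points near the top left are Mettl7a2 and Gm20537, which had 0 counts in WT and were chosen after their values were seen.

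Serpinb1a, an inhibitor of neutrophil serine proteases, had the largest rise in Lgmn KO of the 10 genes named by the fixed rule (3.99-fold, with a standard error of 0.32 on the log2 scale, adjusted p = 0.0486), from 2.58 ± 0.614 to 10.3 ± 4.08 CPM (SD, n = 3 each). Stap1, an adaptor of tyrosine kinase signalling, rose by 1.53, Nmnat1, an enzyme of NAD synthesis in the nucleus, by 1.51, and Bcl2l2, which encodes the survival protein Bcl-w, by 1.49 on the log2 scale. Dio2, the deiodinase that activates thyroid hormone, was the most abundant of them and rose from 411 ± 37.7 to 1030 ± 243 CPM (SD, n = 3 each). Slc7a2, a transporter of arginine and other cationic amino acids, rose by 1.32, Htr2b, a serotonin receptor, by 1.29 and Nin by 1.28. Cmbl rose by 1.41 and Atp10d, annotated as a polymorphic pseudogene in GENCODE M21, by 1.25. The adjusted p of these 10 genes lay between 0.00226 for Nin and 0.0486 for Serpinb1a in the edgeR quasi-likelihood test. Nin passed in all 6 fits without 1 library. The other 9 lost their call without Lgmn KO replicate 2 (Serpinb1a then had a log2 fold change of 1.65) and without WT replicate 3. Exons of Bcl2l2, Htr2b, Dio2, Nin and Slc7a2 overlap exons of other annotated genes, and strand use in counting is not given in the sources used here, so reads of these neighbours cannot be told apart.

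**Figure D2:**
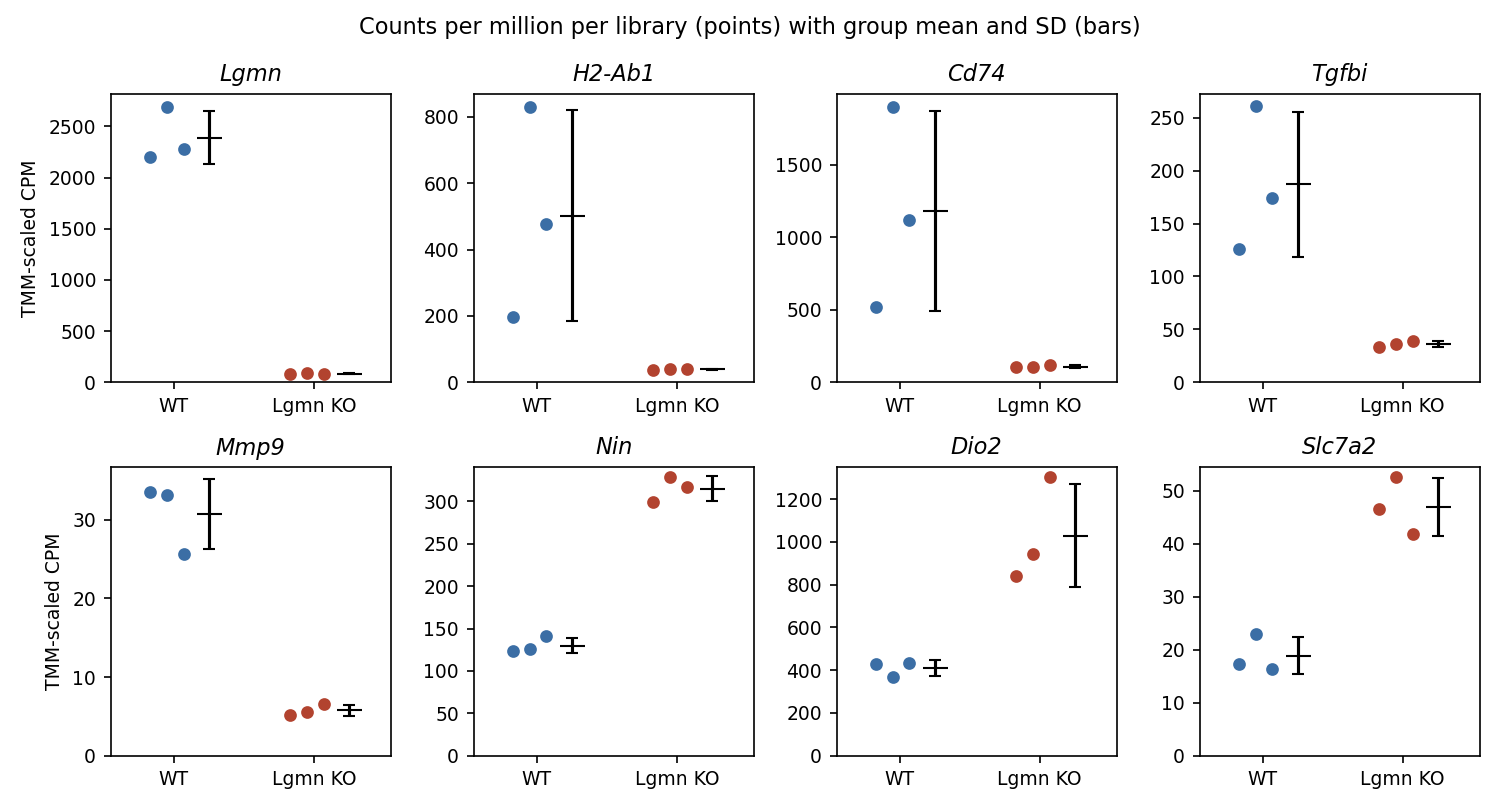
TMM-scaled CPM (vertical axes, from 0) of 8 genes in each WT library (blue points) and each Lgmn KO library (red points), with black bars for group mean and SD, n = 3. Lgmn, H2-Ab1, Cd74, Tgfbi and Mmp9 are lower and Nin, Dio2 and Slc7a2 higher in all 3 Lgmn KO libraries, and H2-Ab1 and Cd74 vary several-fold between WT libraries.

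Transcripts of MHC class II, the molecules that present peptides to helper T cells, were called lower in Lgmn KO as a list by camera with the preset correlation of 0.01 (adjusted p = 2.55e-08) and not with an estimated correlation (adjusted p = 0.435). All 12 tested members of the list had a negative log2 fold change, with a median of -2.02, and 4 fell by the test over all genes, 9 when adjusted over the list alone. Without WT replicate 2 the median was -1.18, and the list was still called with the preset correlation. H2-Ab1 was at 39.3 ± 1.71 CPM in Lgmn KO and 502 ± 318 CPM in WT (SD, n = 3 each), a log2 fold change of -3.67 with a standard error of 0.48 (edgeR quasi-likelihood test, adjusted p = 0.0277). The log2 fold change was -3.61 for H2-Aa, -3.46 for Cd74 and -3.42 for H2-Eb1. The 3 Lgmn KO libraries were close to each other, whereas WT libraries ranged from 521 to 1902 CPM for Cd74. Transcripts of T and NK cells were also lower in Lgmn KO, with 3.54 ± 0.950 CPM summed over 27 low-level markers against 21.4 ± 8.64 CPM in WT (SD, n = 3 each). Low-level markers of endothelial cells summed to 3.80 ± 0.305 CPM in Lgmn KO and 15.2 ± 2.19 CPM in WT, and those of dendritic cells to 9.89 ± 1.96 and 25.6 ± 11.7 CPM (SD, n = 3 each). Of these endothelial markers Flt1 alone was at 1.19 ± 0.257 CPM in Lgmn KO and 8.31 ± 2.51 CPM in WT (SD, n = 3 each). Over all 12 tested endothelial members the sum was not lower in Lgmn KO (825, 963 and 915 CPM) than in WT (733, 737 and 841 CPM). Most of that sum came from Fabp4 and Vwf (means of 653 and 179 CPM in Lgmn KO, 529 and 145 CPM in WT), so it says little about the other members. H2-Ab1, H2-Aa, Cd74 and H2-Eb1 each lost their call without any 1 Lgmn KO library or without WT replicate 3, and without WT replicate 2 the log2 fold change of H2-Aa was -3.004.

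Inflammatory cytokines, chemokines and mediators were called lower as a list with the preset correlation (adjusted p = 1.1e-10) and not with an estimated correlation (adjusted p = 0.435). Of 31 tested members 27 had a negative log2 fold change, the median was -1.13, 5 fell by the test over all genes and 18 when adjusted over the list alone. The CPM summed over the list were 620, 892 and 843 in Lgmn KO replicates 1, 2 and 4. In WT replicates 1, 2 and 3 they were 852, 1310 and 926, so WT replicate 1 lay within the Lgmn KO range. Irg1 (also Acod1), which makes the antimicrobial metabolite itaconate, was at 3.19 ± 1.04 CPM in Lgmn KO and 49.7 ± 33.4 CPM in WT (SD, n = 3 each), a log2 fold change of -3.96. The cytokine gene Il1b fell by 2.84 and the receptor gene Tlr2 by 1.22 on the log2 scale. Saa3, the most abundant member, had a log2 fold change of 0.57 (adjusted p = 0.369). Among the 10 named genes with the largest fall were also the chemokine gene Ccl9, with a log2 fold change of -2.78, and Il21r, which encodes a cytokine receptor, with one of -3.16. Irg1 and Il21r lost their call without any 1 Lgmn KO library or without WT replicate 3, Ccl9 lost it without any 1 library but WT replicate 1, and without WT replicate 2 the log2 fold change of Irg1 was -3.27.

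Type I interferon response genes were called lower as a list with the preset correlation (adjusted p = 2.55e-08) and not with an estimated correlation (adjusted p = 0.544). Of 37 tested members 34 had a negative log2 fold change, with a median of -0.80, 0 passed over all genes by the edgeR quasi-likelihood test (25 had an unadjusted p under 0.05, and DESeq2 called 13), and 18 fell when adjusted over the list alone. Zbp1, a sensor of nucleic acids, had a log2 fold change of -2.10 (adjusted p = 0.0555), and Xaf1, which encodes an antagonist of an apoptosis inhibitor, of -0.95 (adjusted p = 0.083). Members chosen after their values were seen were the interferon-induced GTPase gene Gbp2, at -3.76 (adjusted p = 0.0916), and Rsad2, at -0.07 (adjusted p = 0.92; edgeR quasi-likelihood test). Whether the fall was particular to type I interferon was not tested. The CPM summed over the list were 841, 942 and 1083 in Lgmn KO replicates 1, 2 and 4 and 1037, 2256 and 1465 in WT replicates 1, 2 and 3. WT replicate 1 thus lay within the Lgmn KO range, and WT replicate 2 stood highest. Markers of monocytes and recruited CCR2-positive macrophages were called lower with the preset correlation (adjusted p = 1.11e-06) and not with an estimated correlation (adjusted p = 0.435). Their median was -0.58 over 28 members, of which 2 fell. Itgal, an integrin subunit of leukocytes, fell by 1.33 on the log2 scale and Ly6i with a log2 fold change of -3.71. When adjusted over the list alone, 1 member rose and 15 fell. Ccr2 itself was at 4.88 ± 1.35 CPM in Lgmn KO and 38.1 ± 28.0 CPM in WT (SD, n = 3 each; adjusted p = 0.0727, edgeR quasi-likelihood test). Its log2 fold change was -2.96, and -2.27 without WT replicate 2. The abundant lysozyme gene Lyz2 had a log2 fold change of -0.08.

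Among 24 matrix genes that macrophages make, Mmp9 and Tgfbi fell, and the list was called lower with the preset correlation (adjusted p = 7.64e-06) and not with an estimated correlation (adjusted p = 0.544). Mmp9, a protease that degrades denatured collagen, was at 5.78 ± 0.722 CPM in Lgmn KO and 30.7 ± 4.46 CPM in WT (SD, n = 3 each; adjusted p = 0.00226, edgeR quasi-likelihood test) and passed in all 6 fits without 1 library. Tgfbi, a matrix protein induced by TGF-beta, fell by 2.36 on the log2 scale, but it did not keep its call in all of these fits. Spp1, which encodes osteopontin and was the most abundant member, had a log2 fold change of 0.31 (adjusted p = 0.214). The list's median was -0.51, with 2 members falling over all genes and 6 when adjusted over the list alone. Low-level fibroblast markers, summed, were at 13.7 ± 6.60 CPM in Lgmn KO and 22.9 ± 4.50 CPM in WT (SD, n = 3 each). Anti-inflammatory and repair mediators were not called as a list (median 0.08, mean -0.28, adjusted p = 0.686): Tgfbi and Retnla fell, the latter with a log2 fold change of -1.70, and 5 members rose and 7 fell when adjusted over the list alone. Igf1, a growth factor, had a log2 fold change of 0.50 (adjusted p = 0.0889) and Gpnmb, at 30902 ± 458 CPM in Lgmn KO and 27064 ± 3284 CPM in WT (SD, n = 3 each), of 0.19 (adjusted p = 0.386).

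Subunits of the vacuolar proton pump, which acidifies lysosomes, all had a positive log2 fold change (18 of 18), with a median of 0.21. Over all genes 0 subunits passed by the edgeR quasi-likelihood test (8 had an unadjusted p under 0.05, and DESeq2 called 3), 3 rose when adjusted over the list alone, and the largest value was 0.53 for Atp6v0d2 (adjusted p = 0.0682). This was the 1 list called higher with the preset correlation (adjusted p = 2.75e-06), and it was not called with an estimated correlation (adjusted p = 0.435). Lysosomal cysteine and aspartic proteases and cystatins were not called (median 0.04, mean -0.27, adjusted p = 0.648), with 3 members rising and 2 falling when adjusted over the list alone. Of its 15 members 7 had an unadjusted p under 0.05, and DESeq2 called 5. Within that list Ctsk, which encodes cathepsin K, rose from 164 ± 6.08 to 277 ± 15.6 CPM (SD, n = 3 each; adjusted p = 0.0126, edgeR quasi-likelihood test). Ctsd and Ctsb, among the most abundant transcripts of all, had log2 fold changes of 0.16 and 0.03 (adjusted p = 0.338 and 0.903). Ctsw, a cathepsin of NK and cytotoxic T cells, had 0, 2 and 0 counts in Lgmn KO and 17, 25 and 19 in WT (adjusted p = 0.0539). Lysosomal hydrolases and membrane proteins were not called (median 0.05, adjusted p = 0.271), and 1 of 39 members fell: Gm2a, the activator protein of ganglioside breakdown, by 0.56 on the log2 scale. When adjusted over that list alone, 3 members rose and 4 fell. An unadjusted p under 0.05 was found for 15, and DESeq2 called 6. Genes of autophagy and LC3-associated phagocytosis were not called either (median 0.07, adjusted p = 0.29), with 1 member rising and 2 falling when adjusted over the list alone. In that list the NADPH oxidase subunit Ncf4 rose by 0.55 and the catalytic subunit Cybb fell by 0.86 on the log2 scale. Ctsk, Gm2a, Ncf4 and Cybb each lost their call in at least 1 of the fits without 1 library.

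Genes for the uptake of apoptotic cells had a median of -0.12 over 34 members, of which 24 were negative. Gas6, a bridging molecule between apoptotic cells and their receptors, fell from 41.8 ± 4.95 to 24.9 ± 0.159 CPM (SD, n = 3 each; adjusted p = 0.0297, edgeR quasi-likelihood test). The complement gene C1qa, whose product coats apoptotic cells, fell by 2.37 on the log2 scale, with C1qb at -2.03 (adjusted p = 0.0519). Gas6 and C1qa each lost their call in at least 1 of the fits without 1 library. The receptor genes Lrp1 and Cd36 had log2 fold changes of -0.01 and 0.09. When adjusted over the list alone, 1 member rose and 8 fell. The list was called lower with the preset correlation (adjusted p = 0.00552) and not with an estimated correlation (adjusted p = 0.544), and the call ended without Lgmn KO replicate 1 (adjusted p = 0.175). Pan-macrophage markers, which include the same C1q genes, had a median of -0.36 over 19 members (adjusted p = 0.00157 with the preset correlation, adjusted p = 0.549 with an estimated correlation), with 1 member falling over all genes, and 1 rising and 9 falling when adjusted over the list alone. Markers of resident cardiac macrophages were not called (median -0.27 over 21 members, adjusted p = 0.116), with 2 members rising and 6 falling when adjusted over the list alone, and were called lower without WT replicate 1 (adjusted p = 0.000819), with DESeq2 (adjusted p = 0.0136) and by limma with sample weights (adjusted p = 0.0297). These calls used the preset correlation, and in the full fit the list was not called by camera with an estimated correlation (adjusted p = 0.772). Among the resident macrophage markers Gas6 fell, and Cx3cr1 was at 1.25 ± 0.436 CPM in Lgmn KO and 4.45 ± 1.39 CPM in WT (SD, n = 3 each; adjusted p = 0.0575, edgeR quasi-likelihood test).

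**Figure D3:**
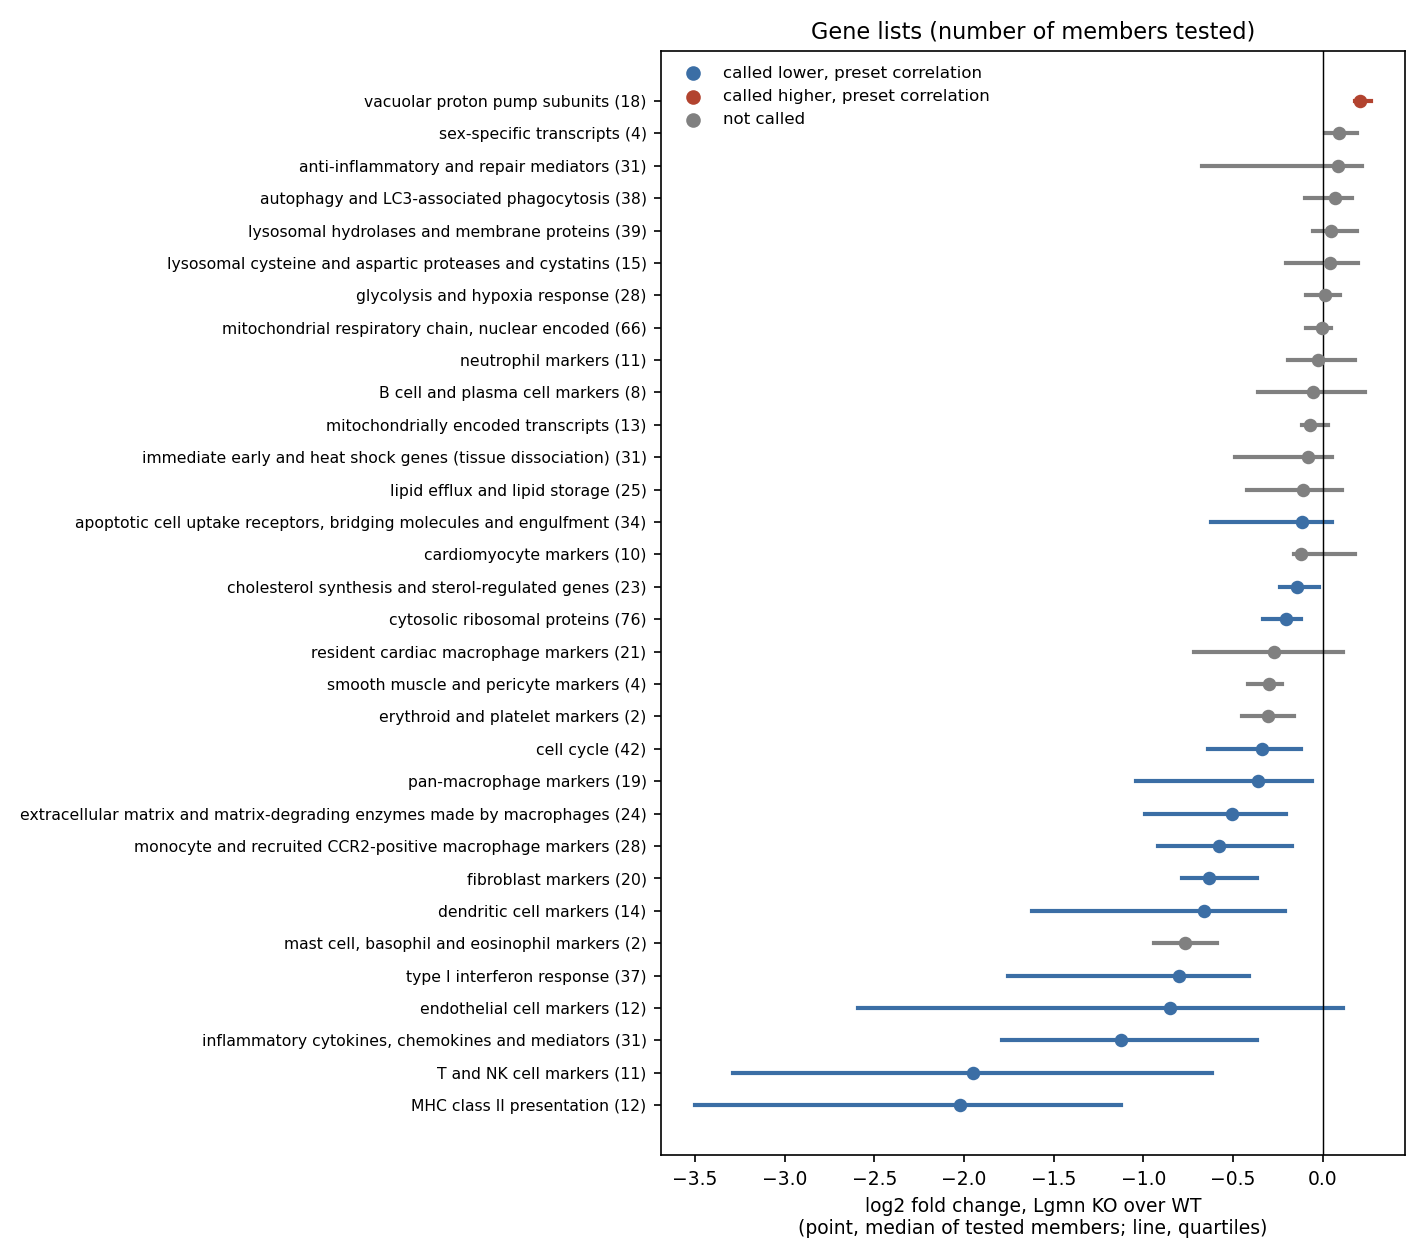
Median log2 fold change of Lgmn KO over WT (points) with quartiles (lines) for the tested members of the 32 gene lists, with the number of members in parentheses; blue lists were called lower, red higher and grey not called by camera with the preset correlation. MHC class II presentation (-2.02) and T and NK cell markers (-1.95) have the lowest medians, and the proton pump (0.21) has the highest.

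Transcripts of other cell types that a heart sort could hold did not move alike. T and NK cell markers had a median of -1.95 over 11 members. The list median of T and NK cell markers was -2.59, -2.93 and -3.36 without Lgmn KO replicate 1, 2 or 4, -3.47 without WT replicate 1, -1.45 without WT replicate 3 and -2.99 without a filter, and it was called lower in each of these with the preset correlation. More low-count genes were tested in these fits (12759 to 12847 without 1 of these libraries and 18457 without a filter, against 12546). The members behind these medians can therefore differ from the 11 of the full fit, so the medians do not show the effect of a library alone. In the full fit Tcf7, Trac and Bcl11b fell. Trac, the constant region of the T cell receptor alpha chain, was at 0.0662 ± 0.0312 CPM in Lgmn KO and 0.990 ± 0.382 CPM in WT (SD, n = 3 each). Il7r, which belongs to the same list, was at 1216 ± 126 and 936 ± 118 CPM (SD, n = 3 each; adjusted p = 0.154, edgeR quasi-likelihood test), far above the other members. Dendritic cell markers had a median of -0.66 over 14 members, and 1 of them, the transcription factor Zbtb46, had a log2 fold change of -2.15 and fell. Endothelial markers had a median of -0.85 over 12 members, with Flt1, a receptor of vascular growth factors, falling by 2.79, and Fabp4 at 0.30 (adjusted p = 0.166). Fibroblast markers had a median of -0.64 over 20 members, with 0 passing over all genes by the edgeR quasi-likelihood test (7 had an unadjusted p under 0.05, and DESeq2 called 2) and Dcn, which encodes decorin, at -1.08 (adjusted p = 0.198). When adjusted over each list alone, 8 members fell and 1 rose for T and NK cells, 3 fell for dendritic cells, 6 fell and 1 rose for endothelial cells and 1 fell for fibroblasts. These 4 lists were called lower with the preset correlation (adjusted p = 1.82e-06, 0.000539, 0.0154 and 0.000605) and none with an estimated correlation (adjusted p = 0.435, 0.435, 0.435 and 0.57). Without Lgmn KO replicate 1 the endothelial and fibroblast calls ended (adjusted p = 0.0594 and 0.0614), and the endothelial call also ended without a filter (adjusted p = 0.157) and by limma with sample weights (adjusted p = 0.0508). By fry, which asks whether a list moves one way without comparing it with other genes, T and NK cell markers were the only one of the 32 lists that passed (adjusted p = 0.0204).

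Lists of cardiomyocyte markers (median -0.12, adjusted p = 0.527), B cell and plasma cell markers (median -0.06, adjusted p = 0.962) and neutrophil markers (median -0.03, adjusted p = 0.781) were not called, and Mmp9 was the only gene in them that passed. The same holds for smooth muscle and pericyte markers (median -0.30, adjusted p = 0.352), for mast cell, basophil and eosinophil markers (median -0.77 over 2 members, adjusted p = 0.0675) and for erythroid and platelet markers (median -0.31 over 2 members, adjusted p = 0.224). The mast cell list was called lower without Lgmn KO replicate 2 or 4 (adjusted p = 0.0296 and 0.0357), without a filter (adjusted p = 0.00122) and with DESeq2 (adjusted p = 0.0395), and the neutrophil list with DESeq2 (adjusted p = 0.0231). These calls used the preset correlation, and in the full fit neither list was called by camera with an estimated correlation (adjusted p = 0.435 and 0.875). Sex-specific transcripts were not called (median 0.09, adjusted p = 0.527), and Kdm5d, on the Y chromosome, was at 31.6 ± 1.23 CPM in Lgmn KO and 32.1 ± 0.784 CPM in WT (SD, n = 3 each).

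Of 76 ribosomal protein transcripts 67 had a negative log2 fold change, with a median of -0.21, and 1 fell by the test over all genes. As a list they were called lower with the preset correlation (adjusted p = 2.53e-08) and not with an estimated correlation (adjusted p = 0.544). The 1 that fell, Rpl3, did so by 0.81 on the log2 scale, from 179 ± 11.0 to 102 ± 4.56 CPM (SD, n = 3 each; adjusted p = 0.0126, edgeR quasi-likelihood test), and Rpl4, the most abundant, was at -0.26 (adjusted p = 0.129). With adjustment over the list alone 16 members fell, and ribosomal genes share sequence with many pseudogenes, so their counts are uncertain. Cell cycle genes had a median of -0.34 over 42 members, with 0 passing over all genes by the edgeR quasi-likelihood test and 0 when adjusted over the list alone (14 had an unadjusted p under 0.05, and DESeq2 called 2), and Top2a, a topoisomerase of dividing cells, was at -0.70 (adjusted p = 0.161). Cholesterol synthesis and sterol-regulated genes had a median of -0.14 over 23 members, with Hmgcs1, an early enzyme of the pathway, at 0.32 (adjusted p = 0.0727), 1 member rising when adjusted over the list alone, and Insig1, a sterol sensor, at -0.31 (adjusted p = 0.116). The cell cycle and cholesterol lists were called lower with the preset correlation (adjusted p = 3.26e-05 and 0.0404) and neither with an estimated correlation (adjusted p = 0.544 and adjusted p = 0.649). The cholesterol call ended without Lgmn KO replicate 2 or 4 or WT replicate 1 (adjusted p = 0.0855, 0.275 and 0.262) and with DESeq2 (adjusted p = 0.0995).

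Lipid efflux and storage was not called as a list (median -0.11, adjusted p = 0.568), with Plin2, a lipid droplet protein, at 2696 ± 342 and 2036 ± 38.9 CPM (SD, n = 3 each; adjusted p = 0.0937, edgeR quasi-likelihood test). Glycolysis and hypoxia response had a median of 0.01 and a mean of -0.01 (adjusted p = 0.958), the nuclear-encoded respiratory chain one of -0.00 (adjusted p = 0.888) and mitochondrially encoded transcripts one of -0.07 (adjusted p = 0.414). Immediate early and heat shock genes, which tissue dissociation can induce, had a median of -0.08 (adjusted p = 0.0887), with Junb at -0.43 (adjusted p = 0.0759) and Hspa8 at 0.02. Without Lgmn KO replicate 2 that list was called lower (adjusted p = 0.0326), and mitochondrially encoded transcripts were called lower without WT replicate 1 (adjusted p = 0.00114) and by limma with sample weights (adjusted p = 0.0347). These calls used the preset correlation, and in the full fit neither list was called by camera with an estimated correlation (adjusted p = 0.57 and 0.838).

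Genes near Lgmn were examined because a targeted allele can carry flanking sequence of another strain. Within 5 Mb of Lgmn 2 of 47 tested genes passed (4.26%), against 96 of 12498 elsewhere (0.768%; two-sided Fisher's exact test, p = 0.052). Within 20 Mb it was 5 of 181 (2.76%) against 93 of 12364 (0.752%; Fisher's exact p = 0.0137). On chromosome 12 beyond 20 Mb, in comparisons chosen after the data were seen, 3 of 237 genes passed (1.27%), against 90 of 12127 on other chromosomes (0.742%; Fisher's exact p = 0.264) and 5 of 181 within the window (Fisher's exact p = 0.301). Among the genes between 5 and 20 Mb away, Dio2 and Adssl1 rose. Bcl11b, also on the list of T and NK cell markers, fell from 42 counts summed over WT to 1 over Lgmn KO. Of these genes, Adssl1 was chosen after its values were seen. The number of called genes within 5 Mb was 0 without Lgmn KO replicate 4 or WT replicate 3, 1 without Lgmn KO replicate 1 or 2 or WT replicate 2, and 8 without WT replicate 1.

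The authors' deposited table also carries their own comparison, with a q-value for 17476 genes. It lists 666 genes at q below 0.05, of which 176 were higher and 490 lower in Lgmn KO, and 422 with at least a 2-fold change. In the authors' deposited table Lgmn has a log2 fold change of -4.85. All 99 genes called by the edgeR quasi-likelihood test were among the genes at q below 0.05 in the authors' deposited table and had the same direction there. Across 12546 genes the p-values of the authors' deposited table had a Spearman correlation of 0.987 with those of edgeR's exact test, which called 709 genes, a correlation across genes, which are not independent replicates.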

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

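The tests chosen after the data were seen are limma-voom without sample weights, edgeR's robust quasi-likelihood fit and edgeR's exact test. Lgmn passed in every fit, with a log2 fold change of -4.89 to -4.75 without 1 library. All 99 genes kept their sign wherever they were tested, which is no sign of stability, since their groups did not overlap. The number of genes (99, of which 39 higher and 60 lower) was 318 (88 and 230) with no filter, 804 (283 and 521) by DESeq2's Wald test, 340 (119 and 221) by limma with sample weights, 46 (21 and 25) by limma-voom without weights, 709 (214 and 495) by edgeR's exact test and 503 (179 and 324) at a threshold of 0.1, and 61, of which 19 higher, with at least a 2-fold change. It was 90 with DESeq2 size factors, 84 with a mean of at least 10 counts and 90 by the robust fit. Without 1 library it lay between 6 and 639 (3 to 169 higher, 3 to 470 lower), highest without WT replicate 1 and lowest without Lgmn KO replicate 2, where 5 of the 99 remained. Lgmn, Nin, Mmp9 and Hnrnpf, the last chosen after its values were seen (log2 fold change 0.96, adjusted p = 0.00626), passed in all 6 of these fits. Genes within 5 Mb of Lgmn numbered 2, and 8 by DESeq2's Wald test, 0 by limma-voom without weights, 7 by the exact test, 0 to 8 without 1 library, and 5 within 20 Mb. Of 14 lists called lower and 1 called higher, 0 and 0 were called with an estimated correlation; with the preset one 11 to 15 were lower without 1 library, and the lists whose calls changed most often were those of cholesterol, endothelial, resident macrophage and mast cell genes. The authors' deposited table lists 666 genes at q below 0.05 and 422 with at least a 2-fold change. With the replicate number as a block, 39 genes passed (9 higher, 30 lower, 1 near Lgmn), of which 16 were among the 99, the cholesterol list was not called and the mast cell list was (adjusted p = 0.23 and 0.0467). Only numbers 1 and 2 occur in both groups, and the deviations of same-numbered libraries correlated at 0.122 and 0.0757, so the numbers were not taken to pair the libraries. The thresholds of 0.1 and of a 2-fold change, and the wider window, move counts by construction; for all other differences, those without 1 library included, the cause was not tested. Alternatives for normalized values were not run. Among named genes that were called, 34 lost their call without Lgmn KO replicate 2, 33 without WT replicate 3, 31 without Lgmn KO replicate 4, 29 without Lgmn KO replicate 1, 19 without WT replicate 2 and none without WT replicate 1, where 27 others gained one. Depth limits the low genes: 3 counts correspond to 0.125 to 0.153 CPM.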

Other observations

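The tests of MHC class II genes and T cell transcripts were chosen only after the result was seen, and so were the genes named in this part outside the naming rule. The tests of other splits, of genes adjacent to Lgmn and of windows around it were chosen before, but what the window tests would show under flanking sequence of another strain was set down only after their values were seen. The tests of chromosome 12 beyond 20 Mb were chosen after the data were seen. CPM in this part are scaled by the library total with TMM factors, except the means of the most abundant transcripts, which are without them.

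The most abundant transcripts were those of lysosome-rich macrophages: Ctsd had a mean of 29733 CPM over the 6 libraries, Psap 29141, Gpnmb 28964 and Ctsb 20063. Lyve1, a marker of some resident cardiac macrophages, had 0 counts in all libraries, Cd163 had 9 in all and Timd4 29. Some genes of other-cell lists were high in both groups, among them Fabp4, a fatty acid carrier (653 ± 33.4 CPM in Lgmn KO and 529 ± 62.4 CPM in WT), and Vwf, the clotting factor of endothelium (179 ± 24.9 and 145 ± 25.4 CPM; SD, n = 3 each). Ciita, the master regulator of MHC class II genes, was at 2.27, 2.25 and 2.17 CPM in the Lgmn KO libraries and at 9.19, 64.2 and 32.8 CPM in WT replicates 1, 2 and 3 (edgeR quasi-likelihood test, adjusted p = 0.0519). The interferon-gamma-induced gene Cxcl9 had 1 count over Lgmn KO and 33, 280 and 116 counts in the same WT libraries.

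A few abundant genes differed over 10-fold within a group: 3 in Lgmn KO and 4 in WT had at least 50 CPM in their highest library. Hal, which encodes histidine ammonia-lyase, was at 477, 505 and 15.4 CPM in Lgmn KO replicates 1, 2 and 4 and at 6.52 to 10.6 CPM in WT. Tmed2 was at 82.6 CPM in Lgmn KO replicate 4 and at 3.50 CPM or less in all other libraries. In WT the spread was in interferon-induced GTPase genes, with Gbp2 at 14.1, 194 and 54.6 CPM and Iigp1 at 0.924, 64.7 and 10.8 CPM in replicates 1, 2 and 3. Ctsl, which encodes cathepsin L, was at 6071 CPM in Lgmn KO replicate 1 and between 1850 and 2499 CPM elsewhere. Mettl7a2 had 51, 48 and 54 counts in Lgmn KO and 0 in WT, at least 54.8-fold higher against 3 counts over the group, and Gm20537 had 69, 61 and 51 against 0, at least 64.8-fold higher; exons of both overlap other genes.

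The real grouping gave 99 genes and the highest of the other splits of the 6 libraries gave 4, so 1 of 10 splits reached the real value. For lists the real grouping gave 15 and the highest other split 16, and 4 of 10 splits gave at least 15. Every other split mixes the genotypes unequally and keeps part of any difference between them, so its calls are not all false ones. With 10 splits no share under 0.05 can be reached.

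MHC class II transcripts were lower in Lgmn KO, and a single WT library as the whole cause was argued against, since without each WT library in turn the highest list median was -1.18. A larger share of all other cell types alike in WT was argued against too, since the highest WT library reached 1.07 times the Lgmn KO mean for summed cardiomyocyte or neutrophil markers and the lowest reached 3.25 times for T and NK cell markers. Summed low-level endothelial, dendritic and fibroblast markers were also higher in WT, with at least 3.34, 1.32 and 1.40 times the Lgmn KO mean in every WT library. For fibroblasts that mean was pulled down by Lgmn KO replicate 1, at 6.12 CPM against 18.1 and 16.9 CPM in replicates 2 and 4. WT replicate 1 was at 19.2 CPM. Over all tested fibroblast and dendritic members, WT replicate 3 (677 and 487 CPM) lay within the Lgmn KO range (551 to 691 and 405 to 492 CPM). Of the single markers 38.5%, 42.9% and 53.3% were above the Lgmn KO mean in every WT library, against 77.8% for T and NK cells. Among the endothelial ones Flt1 alone was at 1.19 CPM in Lgmn KO and 8.31 CPM in WT. Over all 12 tested endothelial members the sums were 825, 963 and 915 CPM in Lgmn KO and 733, 737 and 841 CPM in WT. Most of each sum came from Fabp4 and Vwf (means of 653 and 179 CPM in Lgmn KO, 529 and 145 CPM in WT), so it says little about the other members. A larger share of some types in WT is thus not excluded, but the markers of each type did not all move together. Dendritic cells in the WT libraries stay open, since their list had a median of -0.66 and its member Zbtb46 fell, with a log2 fold change of -2.15. The most abundant members of that list, Irf8 and Cd24a, were at -0.07 and 0.09, and sorting of cells stained for CD64 may select against dendritic cells. A lower expression of class II genes by the macrophages themselves may explain the pattern as well, which was not tested.

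Called genes were more frequent within 20 Mb of Lgmn than elsewhere. On chromosome 12 beyond 20 Mb, 3 of 237 genes passed, Nin, Slc38a6 and Fut8 (the last 2 chosen after their values were seen), a share that passed the threshold neither against other chromosomes (Fisher's exact p = 0.264) nor against the window (Fisher's exact p = 0.301), so how far the excess extends is left open. An effect of the altered allele on adjacent genes was argued against, since the median absolute log2 fold change within 1 Mb was 1.13 times that of all genes. Flanking sequence of another strain may explain this, but Fisher's exact p was 0.052 within 5 Mb and 0.0137 within 20 Mb. With few genes and no sequence reads used here, flanking sequence cannot be told apart from an effect of legumain on these genes. Bcl11b, among the 5 genes called within 20 Mb, is also on the T and NK cell list. A few T cells in the WT libraries may therefore explain its call as well, which was not tested.

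T cell transcripts were lower in Lgmn KO. Of 27 markers under 5 CPM, 77.8% were above the Lgmn KO mean in every WT library, which lies between the values set for and against a few T cells in the WT libraries, so this explanation stays open, although staining for CD64 and CD11b selects against T cells. Cd8a had 0 counts in Lgmn KO and 7, 36 and 18 in WT, and Trbc2 had 0 against 9, 24 and 19. The most abundant markers Il7r and Cd28 had log2 fold changes of 0.38 and -0.22. Il7r had 74423 counts over Lgmn KO and 62268 over WT, far above Cd8a and Trbc2, so its level cannot show whether a few T cells were present. Whether the sorted fraction or the heart held more T cells was not tested.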
